A study of Rattus norvegicus with 11 samples.

How the data were processed

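RNA from isolated adult ventricular myocytes of 6 male and 5 female Sprague Dawley rats aged 3 to 4 months was used. Per the labels' protocols, total RNA with an integrity number of at least 9 was depleted of ribosomal RNA, and paired-end stranded total RNA libraries were made from 650 ng. Per the submitters' processing notes, the tools were FastQC, Trimmomatic 0.32, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq with the rat genome build rn6, and the notes give neither their order nor their settings. Whether reads were counted by strand, and which gene annotation was used, is not given in the sources used here.

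A single table held the results for 17257 genes. Per the file headers, the authors gave for each gene a mean normalized signal over all libraries and over each of 2 groups, which are gene counts scaled by size factors. The authors also gave a fold change as a linear ratio of the group means, its log2 value, a deposited p-value and its adjusted value. The table names its groups A and B. In all 13346 genes with a mean above 0 the overall mean equalled 6 parts of A and 5 parts of B over 11, within a relative difference of 1e-09, and it did so in 0 genes with the parts exchanged. Group A was therefore read as the 6 males and group B as the 5 females, and fold changes are female over male. The adjusted p-value matched a Benjamini-Hochberg adjustment over the 13346 genes, with a largest difference of 3.3e-15.

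Since the table gave group means and no value per library, the authors' adjusted p under 0.05 was taken as deposited, with no new test across libraries for the full set of genes. Replicate spread is therefore not shown for most genes, and group means are given without an SD. Gene lists were fixed before the data were examined, as were the alternatives and the rule for named genes. Each list was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed z of the authors' p, with a preset correlation of 0.01, and adjusted by Benjamini-Hochberg over 32 lists. The median log2 fold change of each list was also placed among 10000 random lists of the same size, matched on mean expression in 50 bins. The genes named were, among genes past the threshold with a mean of at least 50 and a gene symbol outside the Y-linked list, the 12 with the largest log2 fold change in each direction. To these were added every measured member of the Y-linked and X-linked lists, up to 4 members with the smallest p and a mean of at least 10 in each other list, and the 5 genes with the smallest adjusted p in each direction outside the Y-linked list. Some genes that this rule names are not reported here. A list fixed for transcripts encoded in mitochondria matched no gene name. Whether such transcripts were counted in rows with an Ensembl identifier alone was not checked.

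Of the 17257 gene names, 14659 were symbols of the RefSeq table of the assembly GRCr8 and 2154 were older symbols there. A further 444 matched neither, 37 of them rows with an Ensembl identifier and no symbol. Of these 37 rows, 30 had reads, and they held 57.5% of the summed male means and 50.7% of the summed female means. Their genes are not named here, and 6 of them were called higher in males, among them ENSRNOG00000030371 and ENSRNOG00000030700 with log2 fold changes of -0.77 and -0.64 in the authors' deposited table. RefSeq coordinates were not used, since the build differs, and the table served for names and for the order of genes.

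Size factors and some reads per library were recovered from the digits of the means, a step added after the data were examined. A group mean multiplied by the number of libraries is a sum of whole reads, each divided by the size factor of its library. Below 2 times the smallest such sum there were 6 distinct values in males and 5 in females, which gave the size factors. Whole reads were then searched for each gene with a male mean up to 30 or a female mean up to 100, within a relative tolerance of 1.5e-14. Exactly 1 solution was found for 3242 of 3242 genes in males and 4487 of 4487 in females, and 3726 genes had reads in all 11 libraries, zeros included. Of 2588 and 3716 values shifted by a relative 1e-09 to 2e-09, 0.116% and 0.215% had a solution. On simulated data with the real means the true reads were returned for 100% of 3150 genes in males and of 4397 in females. Libraries are thus known by sex and size factor, not by replicate number, and carry the letters a onwards within a sex in order of falling size factor.

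For 899 of these genes with a mean of at least 10, limma was run on log2 of the normalized read count plus a pseudocount of 1. On data simulated with the real means, the recovered size factors and an assumed dispersion, with 200 of 899 genes changed, it called 0.5% of genes changed 1.5-fold, 24.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 13 calls among unchanged genes in the last case. The list test was tried on z simulated independently for each gene, whereas the real values correlate between neighbouring genes. Its rates therefore do not measure false calls in these data. The test called 2% of unshifted lists of at least 20 members at an unadjusted p of 0.05. It called 20.5% of lists shifted by 0.25 SD and 67.75% of lists shifted by 0.5 SD, in 400 simulated list tests each. Of 462 possible splits of the libraries, 100 were drawn with the split by sex included. They were also compared in the 369 genes with a mean over all libraries from 10 to 16.4, a range in which reads are recovered whatever the means of the sexes. Exact permutation tests were run with scipy 1.17.1, and counting intervals are exact 95% Poisson intervals that cover counting error only. Other work used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

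The alternatives tried were adjusted p thresholds of 0.01 and 0.1, means of at least 10 or 50 with the p-values adjusted again, a fold of at least 1.5, centring, leaving out the sex-linked lists, and other settings of the list test. For the log2 fold change as its statistic, 1 was added to each mean because some means are 0, a detail set after the data were seen. A second test, leaving out libraries and a replicate block were planned for values per sample and were not run for the full table. Gene symbols did not repeat, so keeping 1 row per symbol had nothing to act on.

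Tests on the order of genes were added after the data were seen. Genes with a mean of at least 50 were placed by the RefSeq table, and log2 fold changes were correlated between genes at several distances and set against 1000 shuffles. The z of each gene was then regressed on the mean z of its 20 nearest such genes, less those that shared a fixed list with it. The lists were tested again on the residuals. A trend shared among members of the same list was therefore not removed. This regression was the sole setting tried. A genome of the build used by the authors was not used here, so base composition itself was not tested.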

Results

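Total RNA was sequenced from ventricular myocytes of adult Sprague Dawley rats, isolated by perfusing the heart on a Langendorff apparatus, plated for 45 minutes without treatment and frozen. There were 6 libraries from males and 5 from females, each a biological replicate per the labels, and the design asked how the sex of the animal relates to gene expression in these contractile cells of the heart. The values used here are the authors' mean normalized counts for each sex, with their fold changes and p-values, for 17257 genes. Of these, 13346 had a mean above 0 and 3911 were listed at 0. The size factors of the 11 libraries, read from the digits of the means, ran from 0.811 to 1.17 in the males and from 0.972 to 1.14 in the females. They did not separate the sexes, with an exact permutation p = 0.442 (two-sided). In 3726 genes with low means, where reads per library could be recovered, the libraries held from 20098 to 28856 reads.

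Eif2s3y, a Y-linked gene for a translation initiation factor subunit, separated the sexes by its group means. In the authors' deposited table its mean was 2215 normalized counts in the male libraries and 0.578 in the female libraries, with an adjusted p of 5.1e-111. The 5 female libraries held 3 reads of it, 1 in each of 3 libraries. Reads per library were not recovered at male means of this size, so the male libraries were not checked singly. The ratio of the male to the female mean was 3831, with a 95% counting interval from 1311 to 18577. Ddx3, which the RefSeq table also knows under the older symbol Ddx3yl, had means of 2341 and 0.206 in the authors' deposited table, with an adjusted p of 1.9e-118. A single read was present in 1 female library, which gave a ratio of 11373 with a 95% counting interval from 2041 to 449221. The RefSeq table lists Ddx3 as an older symbol of Ddx3y as well, so the reads of these near-identical genes could have been divided between them. The row named Ddx3y had a normalized read count of 7.84 ± 5.86 (SD, n = 6) in males and 13.6 ± 9.57 (SD, n = 5) in females, with an exact permutation p = 0.290 (two-sided). It was therefore not read as a measure of the Y-linked copy. Tspy1, the remaining measured member of the Y-linked list, had a male mean of 0.822 and was listed at 0 in females.

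X-linked genes listed as candidates for escape from inactivation moved in both directions where they were measured. Of 18 listed genes, 11 were measured. Xist, planned as a check of the sex labels, was not among them, nor were Kdm6a and Kdm5c. Of 11 measured members of that list, Uba1, a ubiquitin-activating enzyme, was higher in females and Smc1a, a cohesin subunit, was lower. Their log2 fold changes (female over male) in the authors' deposited table were 0.40 and -0.40, with adjusted p-values of 0.0308 and 0.0218. Adjusted over the list alone, 2 members were higher and 2 lower. Eif2s3x, the X-linked partner of Eif2s3y, had a log2 fold change of 0.33 and Usp9x one of -0.33, with adjusted p-values of 0.0688 and 0.0758 in the authors' deposited table. The remaining members measured, Ddx3x, Pbdc1, Zfx, Mid1, Med14, Utp14a and Cdk16, also missed the threshold. Among them Zfx and Mid1 had the largest log2 fold changes of the list, -0.53 and -0.50, with adjusted p-values of 0.122 and 0.368 in the authors' deposited table. The list test gave an adjusted p of 0.517.

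The sexes differed in many genes by modest folds. At an adjusted p under 0.05 in the authors' deposited table, 1932 of 13346 genes differed, which is 14.5%. Of these, 896 were higher in females and 1036 were higher in males. The median fold was 1.51 among the former and 1.56 among the latter, leaving out 3 genes listed at 0 in one sex. A fold of at least 2 was reached by 61 of the genes higher in females and by 128 of those higher in males. The median log2 fold change of the 9116 genes with a mean of at least 50 was -0.0028.

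**Figure D1:**
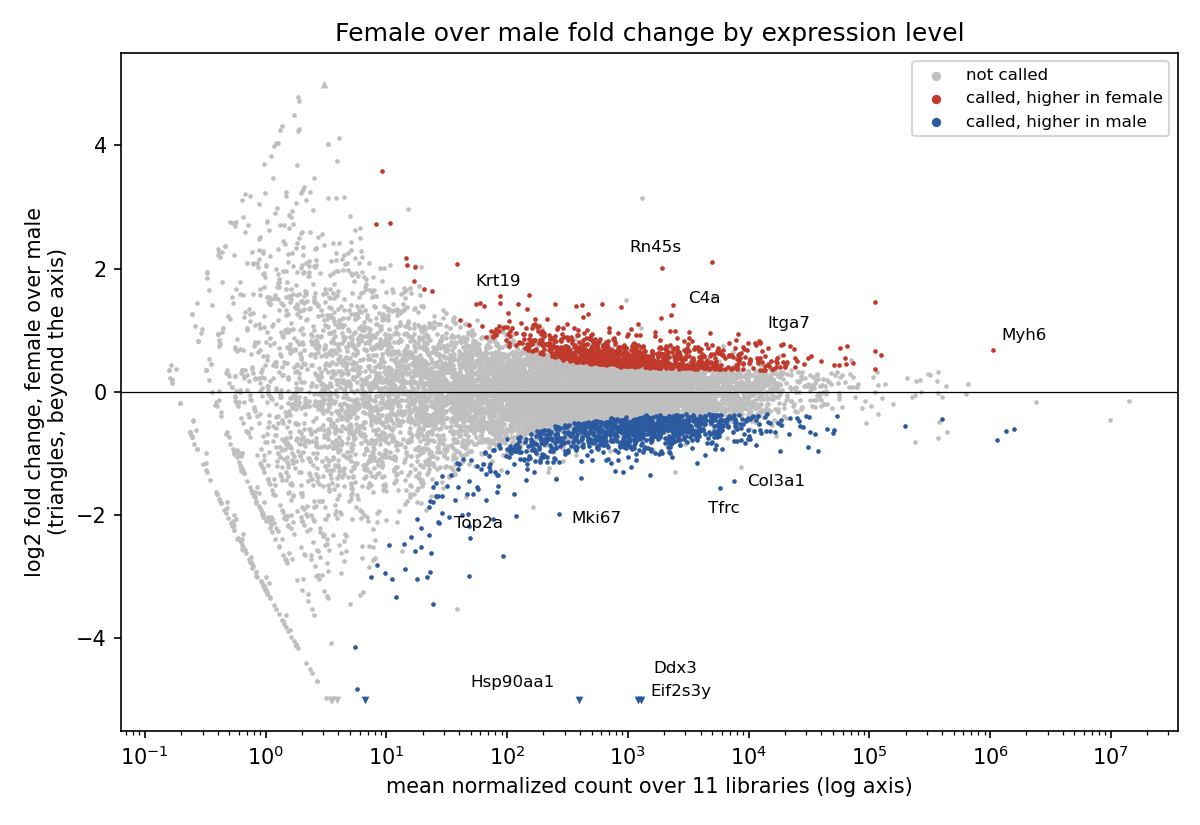
Log2 fold change (female over male, vertical axis) against the mean normalized count over 11 libraries (horizontal log axis), both from the authors' deposited table, one point per gene with a finite fold. Red points are the genes called higher in females and blue points those called higher in males at an adjusted p under 0.05, and triangles mark values beyond the axis, among them Ddx3, Eif2s3y and Hsp90aa1.

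Among genes higher in females, those with the smallest p-values in the authors' deposited table were Synpo, C4a, Itga7, Por and Nr4a1. Synpo encodes the actin-associated protein synaptopodin, and its mean rose from 1157 in males to 2270 in females, with an adjusted p of 1.5e-07 in the authors' deposited table. C4a, a complement component, had means of 1417 and 3354, a fold of 2.37 in the authors' deposited table. Itga7, the laminin-binding integrin subunit of striated muscle, had a fold of 1.77, and Por, the electron donor to microsomal cytochrome P450 enzymes, one of 1.83 in the authors' deposited table. By size of change, among called genes with a mean of at least 50 and a gene symbol, the highest was Rn45s, the ribosomal RNA precursor. Its fold was 4.01 in the authors' deposited table. The libraries were depleted of ribosomal RNA, and whether the depletion differed between libraries was not tested. Next came Ier5l with a log2 fold change of 1.57 and Terc, the telomerase RNA, with 1.56 in the authors' deposited table. They were followed in the authors' deposited table by Rmrp (1.45), Krt19 (1.45), Ass1 (1.45), Map1s (1.43), Cyp2e1 (1.43), Slc52a3 (1.42), Lrg1 (1.42), Selplg (1.41) and Hist2h4 (1.41). The RefSeq table gives Rmrp as an older symbol of Rpph1, so which of these short RNAs the row counted is uncertain.

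Among genes higher in males, Tfrc, the transferrin receptor that brings iron into cells, had the smallest p after Ddx3 outside the Y-linked list. Its mean was 8298 in males and 2813 in females, a log2 fold change of -1.56 with an adjusted p of 9.9e-26 in the authors' deposited table. Sh3bgrl, Rcn1 and Casc5 came next, with log2 fold changes of -1.10, -1.01 and -2.99 in the authors' deposited table. The genes given next were among those with the largest changes at a mean of at least 50. The log2 fold change in the authors' deposited table was -2.66 for Prc1, -2.07 for Cenpf, -2.01 for Top2a, -1.99 for Mki67, -1.75 for Ckap2 and -1.66 for Aspm. Pycard (-1.63), the chemokine gene Ccl4 (-1.58) and Tfrc were also among them, again in the authors' deposited table. Hsp90aa1, an inducible form of the chaperone Hsp90, stood apart with authors' means of 720 in males and 2.12 in females and an adjusted p of 0.0017 in the authors' deposited table. Its reads can be shared with its many pseudogenes, so this value is uncertain. The females held 11 reads of it in 3 libraries.

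The gene lists were tested as sets on the signed z of the authors' p-values with a preset correlation of 0.01 between genes. Of 32 lists with a measured member, 13 passed an adjusted p of 0.05, 10 of them higher in females and 3 higher in males. With a preset correlation of 0.05 only the Y-linked list kept its call, with an adjusted p of 4.1e-10. That list has 3 measured members, of which Eif2s3y alone was called, and on ranks it lost its call, with an adjusted p of 0.537. Among the others that lost it, the adjusted p ranged from 0.0527 for the cell cycle list to 0.227. A correlation between genes could not be estimated from group means.

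**Figure D2:**
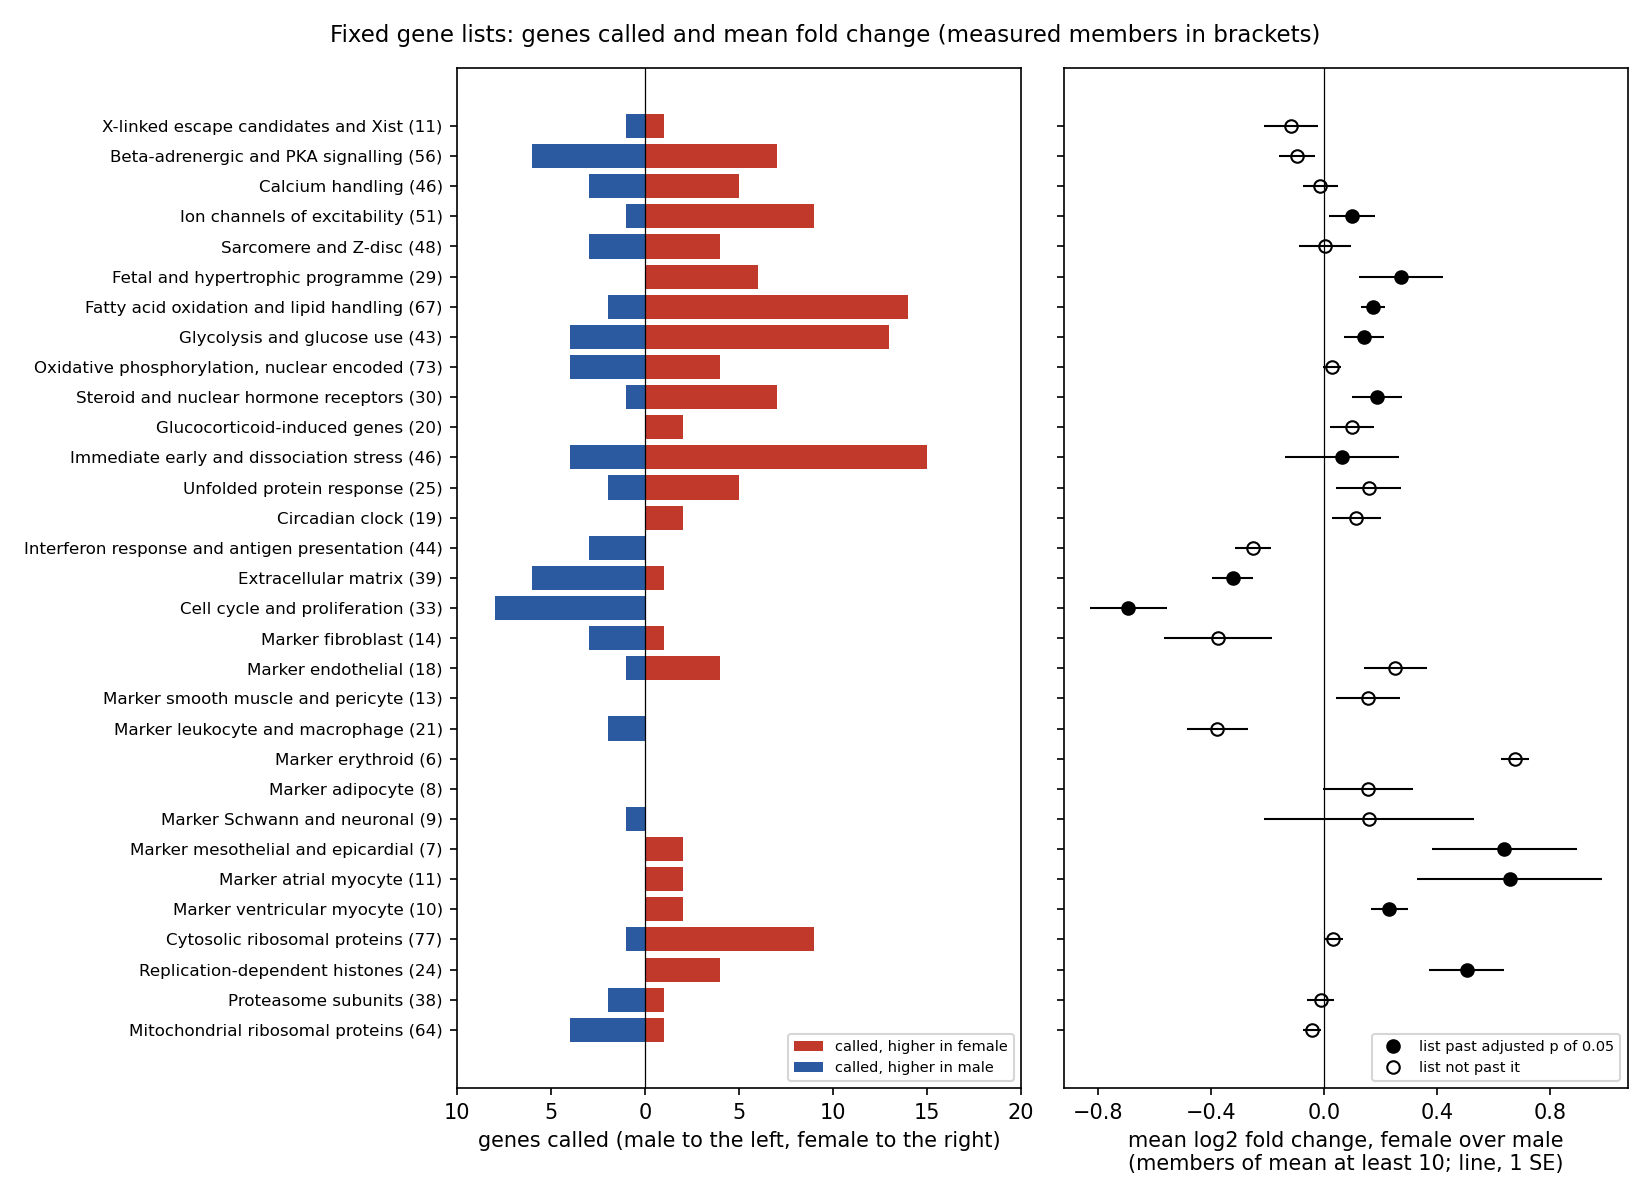
Left, the number of genes called in each list, higher in females to the right and higher in males to the left. Right, the mean log2 fold change (female over male) of members with a mean of at least 10, with 1 SE over members; filled circles are lists past an adjusted p of 0.05, among them the cell cycle list with 0 and 8 genes and the fatty acid list with 14 and 2.

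Genes of fuel use leaned towards females. Of 67 measured genes of fatty acid oxidation and lipid handling, 14 rose and 2 fell in females, with 17 and 4 adjusted over the list alone. Acacb, whose product restrains fatty acid entry into mitochondria, and Mlycd, which removes the product of Acacb, were both higher, by 1.76-fold and 1.55-fold in the authors' deposited table. The mitochondrial uncoupling protein gene Ucp2 was 1.94-fold and the fatty acid transporter gene Slc27a1 1.64-fold higher in the authors' deposited table. The list had an adjusted p of 0.0012, and its median log2 fold change of 0.21 lay at percentile 99.95 of 10000 random lists matched on expression. With the log2 fold change as the statistic, its adjusted p was 0.0983. Of 43 genes of glycolysis and glucose use, 13 rose and 4 fell, and 17 and 5 adjusted over the list alone, with an adjusted p of 0.0360 for the list. Muscle glycogen phosphorylase Pygm rose 1.46-fold, aldolase Aldoa 1.67-fold and hexokinase Hk1 1.53-fold, while Pdha1, a subunit of pyruvate dehydrogenase, had a log2 fold change of -0.61 in the authors' deposited table. The call of the glycolysis list was lost on ranks (adjusted p = 0.102) and on log2 fold changes (adjusted p = 0.223). Nuclear genes of oxidative phosphorylation went both ways, with 4 higher and 4 lower among 73, the same counts adjusted over the list alone, and a list adjusted p of 0.328. Cycs, Cox6c and Atp5j2 fell by 0.67, 0.61 and 0.45 on the log2 scale and Cox6a2 rose by 0.46 in the authors' deposited table.

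Genes of membrane excitability also leaned towards females, whereas those of calcium handling and adrenergic signalling were divided. Of 51 ion channel and pump genes, 9 rose and 1 fell, and 12 and 2 adjusted over the list alone, with a list adjusted p of 0.0360. The sulphonylurea receptor Abcc8 rose 1.66-fold and phospholemman Fxyd1 1.38-fold in the authors' deposited table. On ranks the adjusted p of this list was 0.0804 and on log2 fold changes it was 0.168. Of 56 genes of beta-adrenergic and protein kinase A signalling, 7 rose and 6 fell, and 7 and 10 adjusted over the list alone. The adenylyl cyclase Adcy6 (log2 fold change 0.52) and the phosphodiesterase Pde4a (0.68) were higher, and the inhibitory G protein Gnai3 (-1.11) and the phosphatase subunit Ppp2r3a (-0.60) lower in the authors' deposited table. Its list adjusted p was 0.683. Of 46 calcium handling genes, 5 rose and 3 fell, and 5 and 5 adjusted over the list alone, with a list adjusted p of 0.805. Jph2 (0.41) and Orai1 (0.60) were higher and Trdn (-0.76) and Micu2 (-0.48) lower by log2 fold change in the authors' deposited table.

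The list for the contractile apparatus did not pass the threshold, with 4 of 48 sarcomere and Z-disc genes higher and 3 lower, both over all genes and adjusted over the list alone, and a list adjusted p of 0.481. Within it Myh6, the main adult myosin heavy chain of the rat ventricle, rose from an authors' mean of 831771 to 1330870, a fold of 1.60 in the authors' deposited table. The intermediate filament gene Des rose 1.58-fold and Synpo2 1.42-fold, and Murc fell by 0.46 on the log2 scale in the authors' deposited table. In the list named for the fetal and hypertrophic programme, 6 of 29 genes rose and none fell, with the same counts adjusted over the list alone and a list adjusted p of 0.0360. The transcription factor gene Mef2d rose 1.65-fold, Nkx2-5 1.89-fold, Gata4 1.49-fold and Nfatc1 1.70-fold in the authors' deposited table. Nppa, the atrial natriuretic peptide gene that gives the programme its usual readout, had a log2 fold change of -0.14 and an adjusted p of 0.992 in the authors' deposited table and was chosen for mention after its value was seen. On ranks this list had an adjusted p of 0.105. The list named for steroid and nuclear hormone receptors also holds steroid enzymes, coactivators and membrane receptors. Of its 30 measured genes, 7 rose and 1 fell, and 8 and 1 adjusted over the list alone, with a list adjusted p of 0.0468. Nr4a1, which is also on the list of immediate early genes, rose 2.15-fold in the authors' deposited table. The steroid enzyme gene Sts rose 1.79-fold and the membrane receptor gene Igf1r 1.60-fold, and the glucocorticoid receptor Nr3c1 had a log2 fold change of -0.74 there. This list lost its call on ranks, with an adjusted p of 0.103, and on log2 fold changes, with 0.168.

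The list of immediate early genes, which cells switch on within minutes of stimulation or handling, and of stress genes was higher in females. Of its 46 genes, 15 rose and 4 fell, and 17 and 4 adjusted over the list alone. Junb rose 1.74-fold, Zfp36 1.69-fold and Klf2 2.26-fold beside Nr4a1 in the authors' deposited table. Of the 10 heat shock genes on it 2 rose and 2 fell, and of the other 36 genes 13 rose and 2 fell, a division made after the values were seen. The list had an adjusted p of 0.00064 and a median log2 fold change of 0.26, at percentile 99.99 of the random lists. With the log2 fold change as the statistic the adjusted p was 0.494. Of 20 glucocorticoid-induced genes, 2 rose, over all genes and adjusted over the list alone, and none fell. These were Per1 (1.66-fold) and Dusp1 (1.78-fold) in the authors' deposited table, while Nfkbia and Klf9 had adjusted p-values of 0.0886 and 0.187 there. The median of this list was -0.0055 where its test pointed to females, with an adjusted p of 0.252. Among 19 clock genes, 2 rose and none fell, also adjusted over the list alone, and these were Per1 and Nr1d1, with log2 fold changes of 0.73 and 0.60 in the authors' deposited table. Of 25 genes of the unfolded protein response, 5 rose and 2 fell, and 5 and 4 adjusted over the list alone. Xbp1 (1.64-fold), Hyou1 (1.52-fold) and Herpud1 (1.51-fold) rose, and Dnajc3 had a log2 fold change of -0.65 in the authors' deposited table. The adjusted p of the clock list was 0.219 and that of the unfolded protein list 0.291.

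The lists for the cell cycle and the extracellular matrix were lower in females. Of 33 cell cycle genes, none rose and 8 fell, and 11 fell adjusted over the list alone. The median log2 fold change was -0.50, below that of all 10000 random lists, and the list had an adjusted p of 6.0e-04. Beside Mki67 and Top2a, the ribonucleotide reductase subunit Rrm2 had means of 74.9 in males and 16.6 in females, and Ccnd2 means of 10605 and 6175 in the authors' deposited table. For 5 members of this list with low means, reads were recovered in each library. Their summed normalized reads were 88.1 ± 28.8 (SD, n = 6) in males and 43.1 ± 17.4 (SD, n = 5) in females, with an exact permutation p = 0.0173 (two-sided), and 4 of the 5 female libraries lay below every male library. Taken singly, the 5 genes had exact permutation p-values (two-sided) from 0.0563 for Ccnb1 to 0.892 for Cdkn2b. These genes are part of the list tested on the same libraries, so the test of their sum is no independent support for it. The list of replication-dependent histone genes went the other way, with 4 genes higher in females, none lower and a list adjusted p of 0.0360. Of 39 extracellular matrix genes, 1 rose and 6 fell, with the same counts adjusted over the list alone and a list adjusted p of 0.0089. Collagen gene Col3a1 fell by 1.45, Loxl2, which encodes an enzyme of collagen crosslinking, by 1.30 and Postn by 1.30 on the log2 scale, and the laminin chain gene Lamb2 rose by 0.58 in the authors' deposited table. Of 44 interferon response and antigen presentation genes, none rose and 3 fell, and 1 fell adjusted over the list alone, with a list adjusted p of 0.0982. This list did not pass the threshold. The genes that fell were the guanylate-binding protein genes Gbp2 and Gbp5 and Ifi44, with log2 fold changes of -0.89, -0.60 and -0.70 in the authors' deposited table.

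**Figure D3:**
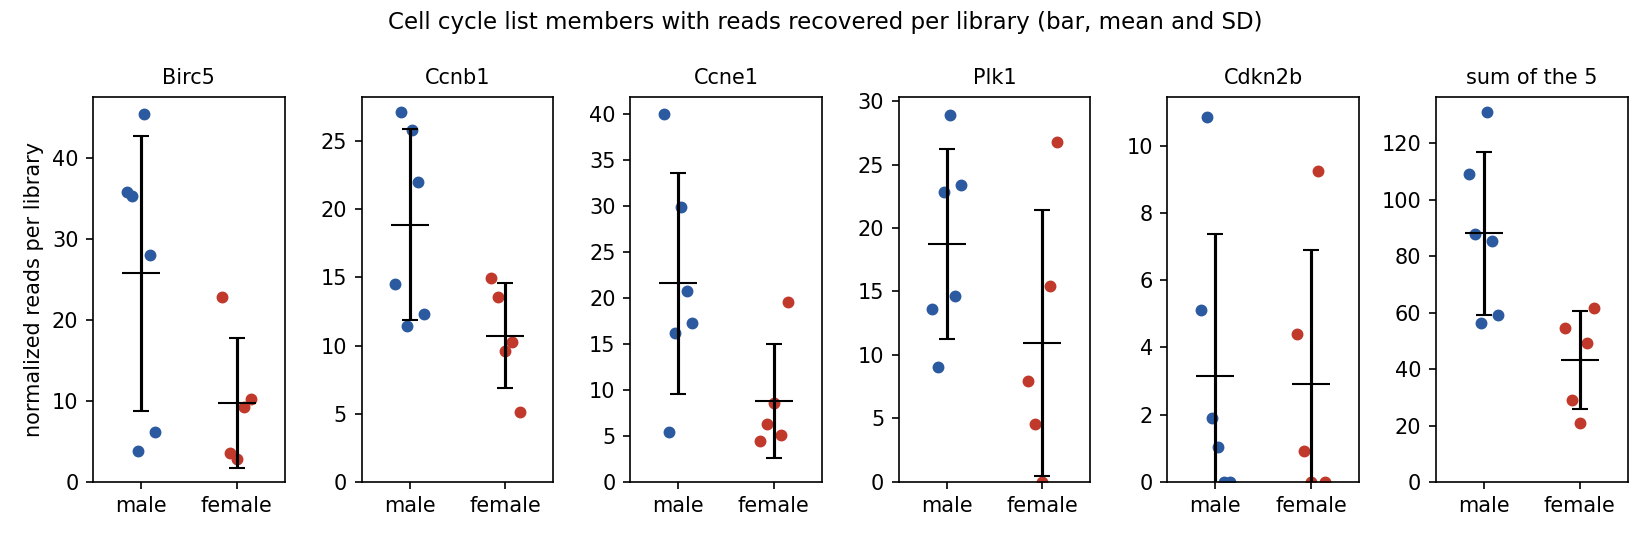
Normalized reads per library (vertical axes) of the 5 cell cycle genes with reads recovered in all 11 libraries and their sum, for 6 male and 5 female libraries. Each point is a library and the bars are the mean and SD. The sums ran from 56.2 to 131 in males and from 21.1 to 61.7 in females.

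Markers of other cell types of the heart moved in different directions. Of 14 fibroblast markers, 1 rose and 3 fell, and 1 and 4 adjusted over the list alone. Col3a1, Postn and Col1a1 fell and Mgp rose, the last with a log2 fold change of 0.70 in the authors' deposited table. Of 18 endothelial markers, 4 rose and 1 fell, with the same counts adjusted over the list alone. Vwf, Egfl7, Gpihbp1 and Eng rose by 1.59-fold, 1.51-fold, 1.66-fold and 1.66-fold in the authors' deposited table. Of 21 leukocyte markers, 2 fell and none rose, and 1 fell adjusted over the list alone. The macrophage receptor gene Mrc1 had a log2 fold change of -1.18 and Lcp1 one of -0.60 in the authors' deposited table. List adjusted p-values were 0.122 for fibroblast, 0.127 for endothelial and 0.169 for leukocyte markers. Without members shared with other lists, the fibroblast list pointed to females, with an adjusted p of 0.764. Of 7 mesothelial and epicardial markers, Krt19 and Msln rose, by 2.73-fold and 2.15-fold in the authors' deposited table, 3 rose adjusted over the list alone, and the list had an adjusted p of 0.0360. This list lost its call on ranks, with an adjusted p of 0.105, and on log2 fold changes, with 0.0835. No marker of smooth muscle (13 genes), red cells (6) or adipocytes (8) passed the threshold, and their list adjusted p-values were 0.328, 0.481 and 0.609. Of 9 Schwann and neuronal markers, Mbp fell, with a log2 fold change of -1.55 in the authors' deposited table and a list adjusted p of 0.604.

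The lists for ventricular and atrial myocytes both leaned towards females, each with a list adjusted p of 0.0360 and 2 genes called, over all genes and adjusted over the list alone. Among 10 ventricular markers, Myh6 and Ryr2 rose, the latter 1.30-fold in the authors' deposited table. Without members shared with other lists the ventricular list had an adjusted p of 0.334, and with the log2 fold change as the statistic one of 0.359. Among 11 atrial markers, Stard10 (1.73-fold) and Tbx5 (1.56-fold) rose in the authors' deposited table. Myl7, the atrial myosin light chain, had authors' means of 287 in males and 2548 in females without passing the threshold, with an adjusted p of 0.427 in the authors' deposited table. On ranks the adjusted p of the atrial list was 0.0595.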

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

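Apart from the list tests on all members and without shared members, the tests of this part were chosen after the data were seen, and of these the tests of cell markers, heat shock genes, a single male library, and gene order in the cell cycle and fatty acid lists were worded or decided after their own or closely related values were known. The search for a library far from the others of its sex covered 26 groups of libraries and found 5. It set the gap to the next library against the range of that sex. For normally distributed values chance gives about 1 in 20. Low read counts need not be so distributed, so whether 5 is an excess cannot be told. Ddx3y had 30.6 normalized reads in female library c against 7.93 to 11.3 in the other females. Aif1, a macrophage marker, had 0 reads in the same library against 11.3 to 13.2 in the other females. Hbb-b1, a globin gene, reached 50.5 in male library f against 1.22 to 15.4 in the other males, and Nr2f1 reached 26.8 in male library d against 5.43 to 12.2. Prph reached 33.2 in male library a, where the gap to the next male was 0.648 of the range of the males.

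The cell cycle list as a set was lower in females, with an adjusted p of 6.0e-04, or 0.0527 with a preset correlation of 0.05. Of its 33 members, 8 were called lower and 25 were not called. Fewer non-myocyte cells of every type in the female preparations is a candidate explanation that the marker means point against without excluding it. Mesothelial markers, picked as the farthest above 0 for its SE of the 5 lists of fibroblast, endothelial, smooth muscle, leukocyte and mesothelial markers, had a mean log2 fold change of 0.64 with an SE of 0.26 over members, and endothelial markers lay above leukocyte markers by 0.63 with an SE of 0.16. The fibroblast list is not used for this, since without members shared with other lists it pointed the other way, with an adjusted p of 0.764. Both SEs are over marker genes, not over libraries, so they do not measure the spread between preparations. The endothelial and leukocyte lists did not pass the list test, with adjusted p-values of 0.127 and 0.169. A single male library as the source of the difference in 5 low-mean members is argued against by an exact permutation p = 0.0317 (two-sided) without the male library of the highest sum. Members with higher means were not tested this way. The trend shared by neighbouring genes outside the list was tested on the 21 of 33 members with a mean of at least 50. There the list had an adjusted p of 0.0680 before the trend was removed and 0.0081 after (unadjusted 0.0117 and 4.2e-04), so it held no call to lose. That the lower p counts against the trend as the whole cause was decided after both values were seen. A change in the share of 1 cell type, such as dividing fibroblasts or macrophages, and the sex of the animals stay open, untested.

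The list of immediate early and stress genes was higher in females, and a stronger general stress of the female preparations could raise heat shock genes too. This cannot be told apart from other causes, because the 10 heat shock members of the list divided, with 2 called higher, 2 lower and a median log2 fold change of 0.13. Named after their values were seen, Bag3 and Hspa1l were higher and Dnaja1 and Hsp90aa1 lower. The trend shared with neighbouring genes outside the list is argued against as the whole cause. The list still passed with that trend removed, with an adjusted p of 0.0094. Its unadjusted p rose from 9.2e-04 to 0.0026, so the trend may account for part of it. The members used had a mean log2 fold change of 0.04, Hsp90aa1 included, and their neighbours one of 0.03 with an SE of 0.04. The time and handling of each heart are not given in the sources used here, and these and the sex of the animals stay open.

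The log2 fold changes followed in part the order of genes along chromosomes. Among 8462 genes with a mean of at least 50 placed in the RefSeq table, the log2 fold changes of adjacent genes had a Spearman correlation of 0.317 across genes, which are not independent replicates, and those 5 places apart one of 0.256. The highest of 1000 shuffles gave 0.0350 and 0.0411. A bias shared by neighbouring genes, such as base composition, is a candidate explanation, and so is regional regulation that differs by sex, which this test does not separate from it. A single library as the carrier cannot be told apart from a difference between the sexes. In low-mean genes the highest exact permutation p with a library left out was 0.0476 (two-sided), but the neighbours' values still include that library and come from the same comparison, so the test excludes nothing. As the whole cause of the fatty acid list the trend of neighbours outside the list is argued against. That list had an unadjusted p of 0.0010 in placed genes and 9.8e-04 with the trend removed, and an adjusted p of 0.0081 after. The sex of the animals stays open, untested.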

How the results depend on the processing

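The low-mean test with its settings and the tests on gene order were chosen after the data were seen. No paired analysis was possible because the table gives no value per numbered replicate. The 1932 genes called became 759 at an adjusted p under 0.01 (394 higher in females, 365 in males) and 1120 with a fold of at least 1.5 (477 and 643). The other settings gave 1929 to 2736 genes, and centring changed no direction. Of the 13 lists past the threshold, 1 list was past it with a preset correlation of 0.05, 6 on ranks and 6 on log2 fold changes, and with members of a mean of at least 50 all 12 that could be tested, the Y-linked list not being among them. Restricted to placed genes with a mean of at least 50, 3 passed. With the trend of neighbouring genes outside the same list removed, 11 lists passed, 10 of them among those 12. The fetal and atrial lists did not (adjusted p 0.174 and 0.144), and the interferon list gained a call (0.0303). Of the 3 marker lists past it, 0 passed with a correlation of 0.05, 1 on ranks and 1 on log2 fold changes. No list past the threshold in either setting changed direction; the fibroblast list, past it in none, pointed to females without shared members. The cause of these changes was not tested. Of 899 low-mean genes, limma called 0, with 112 at an unadjusted p under 0.05. It called 9 with a pseudocount of 5, 1 of 1763 with a mean of at least 3, and 3 of 369 entered by their mean over all libraries alone. The authors' adjusted p called 19 of the 899, and 3 when adjusted over them alone. Leaving out 1 library gave 0 to 5 calls, with 5 without female library d, 4 without female b or c, and 1 without male d or female e. In data simulated with an assumed dispersion it called 24.5% of 2-fold and 98.5% of 4-fold changes, and whether depth limits the real count was not tested.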

Other observations

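The tests on gene order and on low-mean genes were chosen after the data were seen, and the count of splits at an unadjusted p was added, and its set of genes then changed, once the counts in 899 genes were known. Of 24 replication-dependent histone genes, 4 rose and none fell in females, with the same counts adjusted over the list alone, and the list had an adjusted p of 0.0360, or 0.151 with a preset correlation of 0.05. Hist1h1d rose 2.02-fold, Hist2h4 2.66-fold, Hist2h2ab 2.61-fold and Hist2h3c2 1.90-fold in the authors' deposited table. In the test on gene order only 5 of the 24 genes were used, and other histone genes were left out as neighbours. A trend shared among histone genes was therefore not tested.

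Genes of protein making and breakdown were divided. Of 77 cytosolic ribosomal protein genes, 9 rose and 1 fell, and 6 and 1 adjusted over the list alone, with log2 fold changes of 0.58 for Rps14 and 0.46 for Rps15 in the authors' deposited table and a list adjusted p of 0.210. Of 64 mitochondrial ribosomal protein genes, 1 rose and 4 fell, with the same counts adjusted over the list alone, among them Mrpl32 and Mrpl18 with log2 fold changes of -0.60 and -0.66 in the authors' deposited table. The list had an adjusted p of 0.291. Of 38 proteasome genes, 1 rose and 2 fell, with the same counts adjusted over the list alone and a list adjusted p of 0.755. Psmb6 rose and Psmc6 and Psma4 fell, by log2 fold changes of 0.37, -0.49 and -0.49 in the authors' deposited table.

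Genes were sorted by the mean z of their 20 nearest genes, less those that shared a list with them. The 2116 genes with the lowest values held 39 calls higher in females and 438 higher in males, and the 2115 with the highest values held 448 and 47. The neighbours' mean z accounted for 23.2% of the variance of z across 8461 genes. The correlation was 0.162 between genes 20 places apart and 0.010 between genes 100 places apart, where shuffles reached 0.0366 and 0.0415. In 818 low-mean genes, the correlation of each library's deviation with its neighbours' z averaged -0.0866 ± 0.0790 (SD, n = 6) in males and 0.0555 ± 0.0748 (SD, n = 5) in females, with an exact permutation p = 0.0216 (two-sided). A sex difference is partly built into this measure, since the neighbours' z comes from the same libraries. Male library d (0.0551) and female library b (-0.0707) each lay within the range of the other sex.

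Among the 899 low-mean genes, the 0 calls of limma were matched or exceeded in 100 of 100 splits drawn from 462 possible splits of the 11 libraries, the highest other split giving 2, so chance cannot be excluded for this count, which at 0 could not have shown otherwise. These 899 genes were entered by their male and female means, which favours the split by sex, so other counts were compared in 369 genes entered by their mean over all libraries alone, from 10 to 16.4. There 42 genes passed an unadjusted p of 0.05, a count reached in 1 of 100 splits, the split by sex itself. The highest other split gave 37, so chance is argued against for that count among the splits drawn, by a narrow margin. It is not excluded, since the remaining possible splits were not examined and the count was chosen after related counts were known. Limma called 3 of these genes, and the highest other split 2. The groups did not overlap in 5 of them, where chance gives 0.433% of genes, or 1.60, but 5 of 100 splits gave as many and another split gave 6, so chance cannot be excluded for this count. All 19 genes called by the authors' adjusted p had an exact permutation p under 0.05, and limma gave them adjusted p-values from 0.0603 to 0.339. The exact tests are no independent support, since these genes were chosen by the same comparison of the same libraries. Named after their values were seen, Irs3 had 15.6 ± 8.17 (SD, n = 6) normalized reads in males and 65.4 ± 11.1 (SD, n = 5) in females, and Ndc80, a kinetochore gene, 27.6 ± 5.26 (SD, n = 6) and 4.62 ± 4.82 (SD, n = 5). Each had an exact permutation p = 0.00433 (two-sided), the smallest that 6 against 5 libraries allow, and the sexes did not overlap in either.

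The libraries differed in how many of 3726 low-mean genes had a read. The number averaged 1953 ± 179 (SD, n = 6) in males and 1873 ± 424 (SD, n = 5) in females, with an exact permutation p = 0.688 (two-sided). It ran from 1409 in female library e to 2549 in female library b, which also held 165 genes read in no other library.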
